A study of Mus musculus with 52 samples.

How the data were processed

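Gene expression was measured on 52 two-colour Agilent oligonucleotide arrays in laser-captured mammary epithelium of female FVB/N mice from a Met tumor model. Per the labels, tissue RNA went through 2 rounds of linear T7 amplification and was hybridised against a universal mouse reference RNA that had gone through 1 round. Each profile was measured on a pair of arrays with the dyes exchanged. The 26 profiles cover 24 tissues of 14 animals, because 2 tissues were hybridised to both array designs in use. The first design carried 18 profiles on 36 arrays. The second design carried 8 profiles on 16 arrays.

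The deposited scanner files hold spot and local background brightness for green and red (intensity, arbitrary units) with 0/1 quality flags, and were written by Agilent Feature Extraction A.7.5.1 for the first design and 9.1.3.1 for the second. The same deposited files hold processed signals (intensity, background-subtracted and dye-normalised by Feature Extraction) and their log10 red over green ratio (log10). The deposited value tables hold a log2 ratio of tissue over reference for each array (log2), made by the authors. The submitters' processing notes name RMA as the only tool, and the normalization behind those tables is not given in the sources used here. Over the spots of an array the deposited log2 ratios correlated with the Feature Extraction ratios, turned to log2 tissue over reference, at r from 0.919 to 0.955. Their slope on those ratios was 0.929 to 0.981 on the first design and 0.787 to 0.834 on the second.

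The comparisons started from the scanner files. Background was subtracted by the normexp method with an offset of 50, each array was normalised by loess with control spots given no weight, and ratios were turned to log2 tissue over reference (R 4.3.3, limma 3.58.1, statmod 1.5.0, data.table version 1.17.8). Spots marked as outliers by Feature Extraction were set to missing. Repeated spots and then both dye orientations of a tissue were averaged, so that the tissue, not the array, was the unit. A probe was present in a tissue when its tissue signal was well above background and above the 95th percentile of the negative control spots on both arrays. Probes were kept when present in at least 0.5 of the tissues of a compared group, and each gene was represented by its brightest probe. Probes were named from the gene reference (assembly GRCm38.p6, used for names and gene order alone): 23351 of the 41174 probes shared by both designs by accession and 10120 by symbol, while 7703 kept the name given on the array.

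Signal limits precision. The median spot stood 9.85 times above its local background on the first design and 5.04 times on the second. Of all spots, 95.3 to 99.2% lay well above background on the first design and 62.9 to 75.3% on the second. The correlation of both dye orientations of a tissue, over genes, was 0.913 to 0.985 on the first design and 0.823 to 0.962 on the second. The number of tissues limits the precision of every comparison.

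The comparisons were made with limma, 2-sided, with Benjamini-Hochberg adjustment at 0.05 over genes. Tumor against normal used the 9 animals with both tissues on the first design and kept the animal as the pairing block. An N and a T tissue with the same number were read as 1 animal. As deviations from the tumor and normal means, a tumor and its own normal correlated over genes at 0.025 to 0.25 in pairs within 1 run. The correlation was -0.26 to -0.17 in pairs split between runs. The likeness of paired tissues thus followed the run, and a shared effect of the animal was not shown apart from it. Adenosquamous against ErbB2-type carcinoma compared 2 with 6 tumors, with the spread taken from a fit to all 18 first-design tissues and the animal as a random block. The difference of the tumor change between adenosquamous and ErbB2-type animals was tested on the tumor minus normal values. Other carcinomas against ErbB2-type carcinoma across both array designs compared 8 with 6 tumors over the probes shared by both designs, with array design in the model and the tissue as a random block. The papillary carcinoma and 1 of the ErbB2-type tumors carry the same animal number, 5033, and were read as 1 animal. This animal thus gave a tumor to each group, which the tissue block does not account for. Means are given with the standard deviation (SD) over tissues, and log2 differences with the standard error (SE) of the fit.

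The 27 gene lists, with 517 entries, covered pathways, epithelial types and the other cell types a captured region could hold. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Described are the lists with an adjusted p under 0.05, and the others are given as counts. Named genes are Met, Erbb2 and Hgf, the 8 largest rises and 8 largest falls past the threshold whose direction held in every pair or whose groups did not overlap (clone and accession names left out), and up to 2 rising and 2 falling members of each described list. Of the genes this rule names, 1 is not reported here and no other takes its place, so fewer than 8 falls are named in the comparisons that held it. The comparisons, lists, naming rule and first set of alternatives were chosen before the data were examined. Differences are given as log2 values, and some also as linear folds.

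The pipeline was tested on simulated data: random values with the fitted spread of each gene, to which known changes were added. At log2 sizes of 0.5, 1 and 2 it recovered 47.8, 76.1 and 97.0% of changes in the paired comparison. The recovered shares were 7.46, 44.8 and 90.9% for adenosquamous against ErbB2-type tumors, 0, 10.4 and 68.2% for the difference of changes, and 13.4, 70.1 and 93.9% across both designs. False calls numbered 8 of 25992, 7 of 25890, 1 of 26139 and 10 of 24918 unchanged genes. The simulated values held no effect of run. In the real data run overlapped with histology and some pairs were split between runs, so these shares and false calls do not cover error from runs.

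Alternatives were the Feature Extraction processed signals, the deposited tables, median centring in place of loess, Aquantile and scale normalization between arrays, 1 dye orientation at a time, no filter on dim probes, all probes, a 2-fold minimum, omission of blocks, runs as blocks, and each tissue or animal left out. Runs are groups of arrays by date in the file headers, the date of signal extraction on the first design and of the scan on the second. The first design holds runs 1, 2 and 3 and the second holds runs 4 and 5. Run 1 takes arrays dated in the same calendar month, and run 2 every first-design array dated outside runs 1 and 3. Run 5 takes every second-design array dated outside run 4. The arrays of runs 1, 2 and 5 thus need not share a date. Permutation tests of correlations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9. The single mammary intraepithelial neoplasia, a pre-invasive lesion, was part of the contrast in the paired comparison alone. In the other fits it formed a group of its own, in which 1 tissue gives no spread. Sequence was not analysed here.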

Results

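Transcript levels were measured in laser-captured mammary epithelium from a mouse model of breast cancer driven by Met, the receptor tyrosine kinase for hepatocyte growth factor. The series title names the diversity of tumor histologies and a link to human basal breast cancer as its subject. All values are log2 ratios of tissue over a common mouse reference RNA. On the first array design, 9 animals each gave a tumor and a normal tissue: 6 with ErbB2-type carcinoma (a histology resembling ErbB2-driven mouse tumors), 2 with adenosquamous carcinoma and 1 with mammary intraepithelial neoplasia (MIN), a pre-invasive lesion. The second design held 4 adenocarcinomas, 1 microacinar carcinoma with squamous areas and 1 papillary carcinoma, plus 1 ErbB2-type tumor and 1 normal tissue that were also on the first design. Probes counted as present made up 71.5 to 97.4% of those in a first-design tissue and 60.5 to 72.1% in a second-design tissue. Profiles of the tissues on both designs correlated over genes between designs at 0.877 for the ErbB2-type tumor of animal 4164 and 0.861 for the normal tissue of animal 3229. Their highest correlations with another first-design tissue were 0.771 and 0.805.

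The first comparison asked how tumor epithelium differed from normal epithelium of the same animal. Tumors carried less transcript of 12 of 16 fat cell, 9 of 19 basal and myoepithelial and 8 of 20 fibroblast genes. They carried more of 11 of 16 genes switched on by MAP kinase signalling and of 12 of 23 genes induced by interferon. As sets, these and 7 other lists passed at the preset correlation, and none (0) of the 12 did with an estimated correlation (adjusted p = 0.0774 to 0.591). Cfd, which encodes the adipocyte product adipsin, was 39.2-fold lower in tumors, and Acta2, the smooth muscle actin of myoepithelial cells, was 10.6-fold lower. Etv1, an ETS transcription factor downstream of growth factor receptors, was 10.3-fold higher, and Dusp6, a phosphatase that inactivates ERK, was higher as well, with a saturated spot in 6 tissues. Of 26192 genes tested with limma, 3632 changed (1433 up, 39.5%, and 2199 down; 1035 up, 61.5%, and 647 down in the 6 ErbB2-type animals alone), and 953 of them changed at least 2-fold (524 up and 429 down). An unadjusted p under 0.05 was reached by 7924.

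Met itself was not called, and whether its probes also detect a Met transgene is not given in the sources used here. Its difference was -0.57 ± 0.27 (SE; n = 9 pairs; adjusted p = 0.181, limma), lower in 7 of 9 pairs, and -0.34 without animal 562, the pre-invasive lesion, with levels of -1.07 ± 0.64 (SD) in tumors and -0.50 ± 0.94 in normals. It was lower in 6 of 6 pairs in 1 run, while the 2 pairs in which it was higher, 4164 and 5033, were split between runs. The 2 other Met probes gave 0.05 and 0.19. Erbb2 differed by -0.11 ± 0.12 (adjusted p = 0.569). Hgf, the ligand of Met, fell by 0.44 on the log2 scale (SE 0.09; adjusted p = 0.0174), in 9 of 9 pairs, while its 3 other probes gave -0.21 to -0.02 and did not pass the test (adjusted p = 0.340 to 0.873).

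The largest rises and falls below are those among genes whose direction held in every pair, as the naming rule requires. Chl1, a neural cell adhesion molecule, rose by 3.49 ± 0.20 (SE; adjusted p = 5.43e-05), though its 2 other probes gave -0.14 and 2.09. St3gal5, the sialyltransferase that makes the ganglioside GM3, rose by 3.27 ± 0.22 (adjusted p = 0.000148). St8sia6, another sialyltransferase, rose by 3.16 ± 0.47 (adjusted p = 0.00477), with other probes at -0.60 to 0.09. Slc16a6, a monocarboxylate transporter family member, rose by 3.25 ± 0.29 (another probe 1.62), and Col11a1, a fibrillar collagen chain, by 3.12 ± 0.36 (other probes 0.14 and 1.25). Etv1 rose by 3.37 ± 0.30 and Dusp6, where saturation limits the size, by 3.06 ± 0.27. Among the falls, C3, the central complement component, changed by -3.84 ± 0.42 (another probe -0.05). Rspo1, a secreted enhancer of Wnt signalling, changed by -3.79 ± 0.49 over 8 pairs, and Rbp4, the retinol carrier, by -3.59 ± 0.43. Krt19, a luminal keratin, changed by -3.46 ± 0.39, Gjb6, a gap junction protein, by -3.80 ± 0.52 (another probe -0.21, call lost with the processed signals) and Armcx4 by -3.83 ± 0.45 (another probe -1.56).

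**Figure D1:**
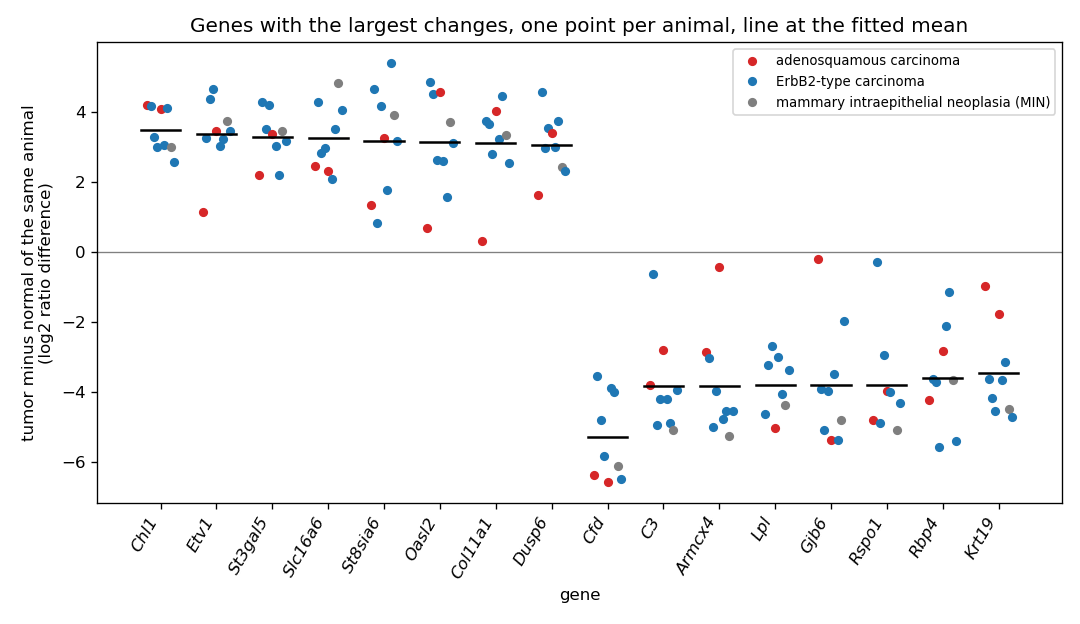
Tumor minus normal difference of the log2 tissue/reference ratio for the 8 genes with the largest rises and the 8 with the largest falls among those whose direction held in every pair, 1 point per animal coloured by histology, with a line at the fitted mean. The means run from 3.49 for Chl1 to -5.29 for Cfd.

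Lists of 4 cell types other than epithelium passed the set test with lower values in tumors, at the preset correlation alone. Of 16 measured fat cell genes 12 fell (13 adjusted over the list alone), among them Cfd (-5.29 ± 0.37, SE) and Lpl, lipoprotein lipase (-3.80 ± 0.27 over 8 pairs, another probe -0.90). The fat cell list had a median difference of -1.62 (adjusted p = 7.8e-11; adjusted p = 0.0774 with an estimated correlation), of -1.67 with run as a block and of -1.17, -2.02 and -0.95 within runs 1, 2 and 3. Of 20 fibroblast and matrix genes 8 fell (9 adjusted over the list alone), including the proteoglycans Dcn (-3.30 ± 0.45, another probe -0.39) and Lum (-2.65 ± 0.30). The fibroblast list had a median of -0.67 (adjusted p = 2.86e-06; adjusted p = 0.369 with an estimated correlation), of -0.63 with run as a block and of -0.84, -0.19 and -1.03 within the runs, and its shift was above 0 in 2 of 9 pairs. Of 14 endothelial genes 8 fell (11 adjusted over the list alone), including the junction proteins Cldn5 (-1.72 ± 0.24) and Cdh5 (-1.38 ± 0.30, another probe -0.12). The endothelial list had a median of -0.69 (adjusted p = 2.01e-05; adjusted p = 0.246 with an estimated correlation), of -0.71 with run as a block and of -0.31, -0.54 and -0.91 within the runs. Of 17 lymphocyte genes 5 fell (6 adjusted over the list alone), including the T cell receptor chain Cd3d (-1.17 ± 0.24) and the B cell receptor chain Cd79b (-0.81 ± 0.18). The lymphocyte list had a median of -0.30 (adjusted p = 0.00152; adjusted p = 0.246 with an estimated correlation), of -0.27 with run as a block and of -0.20, -0.54 and -0.26 within the runs. The skeletal muscle list stood at 0.94, 0.64 and 0.52 in the normal tissues of animals 5154, 5033 and 5156 and at -1.05 to -0.24 in the other 6. Without these 3 animals, a choice made after seeing the data, 346 genes changed (190 up and 156 down), of which 335 were among the 3632 with the same direction.

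Some genes of contractile and secretory mammary cells also fell. Of 19 basal and myoepithelial genes 9 fell (10 fell and 2 rose adjusted over the list alone), led by the contractile proteins Acta2 (-3.41 ± 0.18, SE; 4 other probes -1.95 to 0.39) and Cnn1 (-2.11 ± 0.12). The basal and myoepithelial list had a median of -0.30 (adjusted p = 0.000173; adjusted p = 0.246 with an estimated correlation), of -0.32 with run as a block and of -0.91, -0.08 and -0.52 within runs 1, 2 and 3. Of 16 milk and secretory genes 4 fell (8 adjusted over the list alone), including Glycam1, a milk mucin (-2.07 ± 0.39 over 7 pairs, with saturated spots in 9 tissues, which limit the size), and Spp1, osteopontin (-2.00 ± 0.46). The milk list had a median of -0.65 (adjusted p = 2.01e-05; adjusted p = 0.246 with an estimated correlation), of -0.62 with run as a block and of -0.76, -0.44 and -0.94 within the runs. Of 25 mesenchymal transition genes 4 fell (5 adjusted over the list alone), including the matrix protease Mmp3 (-3.27 ± 0.64, 7 of 8 pairs) and the transcription factor Snai2 (-2.04 ± 0.37). The mesenchymal list had a median of -0.32 (adjusted p = 0.0129; adjusted p = 0.57 with an estimated correlation), of -0.31 with run as a block and of -0.37, 0.04 and -0.60 within the runs. Beside these lists, the fat cell list stood at -1.62 and the fibroblast list at -0.67.

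Members of 3 signalling and response lists rose. Of 16 measured MAP kinase output genes 11 rose (13 rose and 1 fell adjusted over the list alone), led by Etv1 and Dusp6. The MAP kinase list had a median of 1.03 (adjusted p = 2.14e-08; adjusted p = 0.0774 with an estimated correlation), of 0.95 with run as a block and of 0.84, 0.78 and 0.66 within runs 1, 2 and 3. Of 23 interferon response genes 12 rose (15 rose and 1 fell adjusted over the list alone), led by the antiviral genes Oasl2 (3.13 ± 0.43, SE) and Ifit1 (2.92 ± 0.50). The interferon list had a median of 1.05 (adjusted p = 2.45e-09; adjusted p = 0.246 with an estimated correlation), of 1.09 with run as a block and of 0.99, 0.71 and 1.34 within the runs. Of 21 immediate early and stress genes 7 rose (11 rose and 4 fell adjusted over the list alone), including the serum response targets Egr1 (2.03 ± 0.41, 8 of 9 pairs) and Egr3 (1.77 ± 0.45, 8 of 9 pairs; another probe -0.18). The immediate early list had a median of 0.60 (adjusted p = 0.000772; adjusted p = 0.275 with an estimated correlation), of 0.50 with run as a block and of 0.55, 0.36 and 0.18 within the runs.

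Hypoxia and glycolysis genes went both ways, and few cell cycle genes passed the test. Of 20 hypoxia and glycolysis genes 7 rose and 3 fell (8 and 3 adjusted over the list alone). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 2.46 ± 0.25 (SE) and Pfkp, a phosphofructokinase, by 1.73 ± 0.17 (other probes -0.01 and 0.87). Ndrg1, a stress-induced gene, changed by -2.83 ± 0.53 and P4ha2, a collagen prolyl hydroxylase, by -1.07 ± 0.23 (another probe -0.06). The hypoxia list had a median of 0.34 (adjusted p = 0.00337; adjusted p = 0.275 with an estimated correlation), of 0.23 with run as a block and of -0.06, 0.31 and 0.47 within runs 1, 2 and 3. Of 33 proliferation genes 4 rose (also 4 adjusted over the list alone), including the spindle factor Tpx2 (0.84 ± 0.15) and the centromeric histone Cenpa (1.13 ± 0.29; another probe -0.13). The proliferation list had a median of 0.43 (adjusted p = 3.45e-05; adjusted p = 0.591 with an estimated correlation), of 0.39 with run as a block and of -0.24, 0.71 and 0.92 within the runs. The calls of the hypoxia and proliferation lists, and of Cenpa and Tpx2, were lost with scale normalization between arrays.

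In the 15 other lists the set test did not pass. No member changed among 13 antigen presentation and 15 macrophage genes, although 6 macrophage genes fell when adjusted over the list alone. The macrophage median was -0.22 (adjusted p = 0.0586) and the skeletal muscle median -0.45 (adjusted p = 0.0604), with 1 of 12 muscle genes down. Rises and falls numbered 2 and 3 of 21 luminal epithelium genes, 2 and 4 of 19 human basal markers (3 and 6 adjusted over the list alone) and 2 and 1 of 14 human luminal markers. They numbered 2 and 2 of 23 growth factor receptors and ligands, 1 and 3 of 24 Wnt pathway genes, 1 and 2 of 14 Notch pathway genes and 1 and 1 of 20 inflammatory cytokines (1 and 0 adjusted over the list alone). Counts were 4 and 3 of 23 lipid synthesis genes (4 and 4 alone), 0 and 2 of 26 oxidative phosphorylation genes, 2 and 2 of 28 squamous genes (2 and 5 alone), 0 and 1 of 4 erythrocyte genes (1 and 1 alone) and 1 and 1 of 10 housekeeping genes (3 and 2 alone). Median, mean and test differed in sign for the Wnt list (0.05, -0.17, down), the Notch list (-0.03, 0.10, down) and the luminal list (0.17, -0.01, up).

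**Figure D2:**
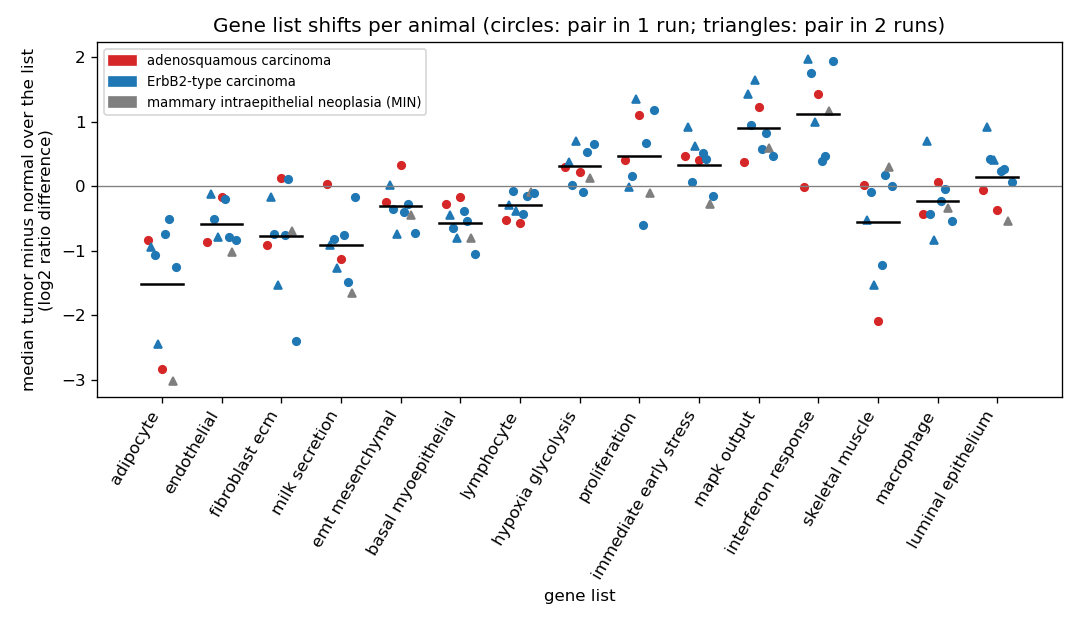
Median tumor minus normal difference (log2 ratio) over each of 15 gene lists, 1 point per animal coloured by histology, circles for pairs in 1 run and triangles for pairs split between 2 runs, with a line at the mean of the 9 animals. The MAP kinase output list lies above 0 in 9 of 9 animals (0.37 to 1.65) and the fat cell list below 0 in 9 of 9 (-3.01 to -0.51).

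None (0) of the 12 list calls held with an estimated correlation. The number of changed genes was 666 in the 6 pairs measured in 1 run. Without pairing by animal it was 656 within run 1, 118 within run 2 and 0 within run 3 (3387 unadjusted, limma), and with pairing it was 1763, 1933, 2299 and 2339 without animals 4691, 559, 5033 and 5156. Of 38 named genes called, 35 were called with any animal left out, while Egr3 (1.46 to 2.17), Cenpa (0.88 to 1.33) and Spp1 (-2.35 to -1.71) were lost without 7, 6 and 4 of the animals.

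The second comparison set the 2 adenosquamous against the 6 ErbB2-type carcinomas, since the study's title names histological diversity. Of 7 lists that passed as sets at the preset correlation, the inflammatory list alone also passed with an estimated correlation (adjusted p = 0.0212, against 0.348 to 0.72 for the 6 others). Trp63, the master transcription factor of basal and stratified epithelium, was 14.8-fold higher, and Krt14, a basal keratin, 4.68-fold higher. Axin2, a feedback target of Wnt signalling, was 16.6-fold higher, a call that rested on tumor 3229: its log2 difference was 1.74 without that tumor (adjusted p = 0.507) and 6.33 without tumor 5154, with an adjusted p of 0.00203 to 0.507 over its alternatives. Cxcl5, a neutrophil chemokine, was 17.9-fold higher. Spdef, an ETS factor of luminal and secretory cells, was 3.41-fold lower. Of 26083 genes tested with limma, 1349 differed (1075 up, 79.7%, and 274 down), 441 of them at least 2-fold (290 up and 151 down), with 4931 at an unadjusted p under 0.05. With median centring in place of loess, 342 differed and the balance turned (140 up, 40.9%, and 202 down).

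Met differed by 0.08 ± 0.63 (SE; adjusted p = 0.961, limma, n = 2 and 6), Erbb2 by -0.38 ± 0.18 (adjusted p = 0.264) and Hgf by -0.04 ± 0.20 (adjusted p = 0.944). Among the rises named by the rule, which asks for groups that do not overlap, the largest was in Sostdc1, a secreted antagonist of BMP and Wnt signals (5.10 ± 0.80, adjusted p = 0.00351), from 0.09 ± 0.14 (SD) in ErbB2-type tumors to 5.19 ± 1.10. St6gal1, a sialyltransferase of glycoproteins, rose by 4.38 ± 0.61 (adjusted p = 0.00173; another probe 0.03), and Trp63 by 3.89 ± 0.52 (adjusted p = 0.00173; other probes 0.11 and 0.53). Armcx4 rose by 3.78 ± 0.85 (another probe 1.25) and Ergic2, a protein of early secretory membranes, by 3.51 ± 0.34 (adjusted p = 6.71e-05). Axin2 (4.05 ± 0.94, adjusted p = 0.0213) and Prr9, an epidermal gene (3.87 ± 0.95, adjusted p = 0.0273), rose with levels that differed widely between both adenosquamous tumors (SD 3.31 and 4.24). Among the falls named here, the largest was in Tesc, a calcium-binding regulator of sodium-proton exchange (-3.86 ± 0.24, adjusted p = 3.84e-07), whose other probe gave -0.03. Palmd changed by -2.86 ± 0.36 (another probe 0.17) and Tspan13, a tetraspanin, by -2.64 ± 0.40. Papln, Wdr72, Ehd3 and the sodium pump subunit Atp1b1 changed by -2.76, -2.70, -2.46 and -2.50. Another probe of Wdr72 gave -0.24.

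**Figure D3:**
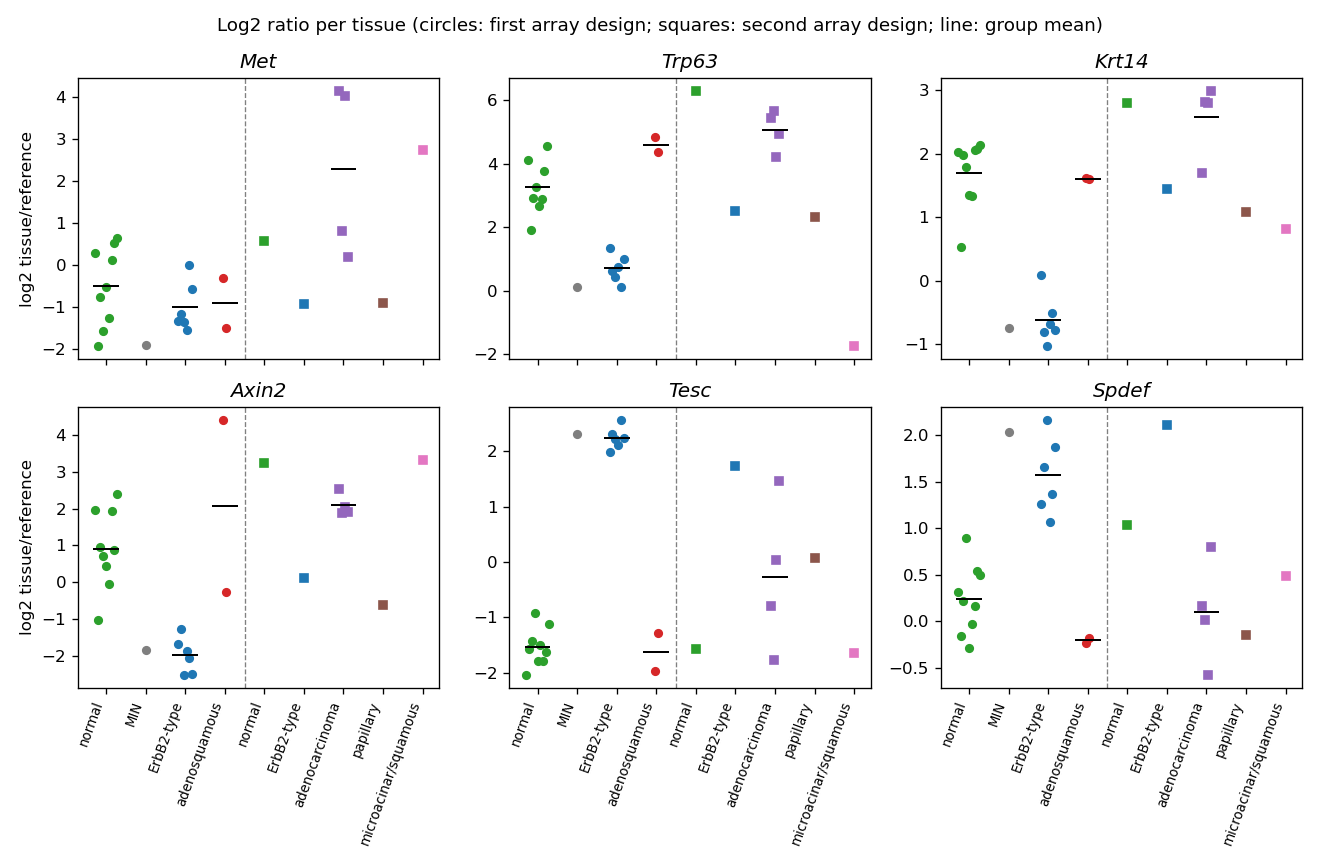
Log2 tissue/reference ratio of 6 genes per tissue, grouped by histology, circles for the first array design and squares for the second, with a line at the mean of groups of at least 2. Met is 4.13 in the highest and 0.19 in the lowest of the 4 adenocarcinomas, while its mean is -0.98 in the 6 ErbB2-type tumors on the first design. The ratios are not adjusted for array design. On the first and second designs Met is -1.32 and -0.93 in ErbB2-type tumor 4164, and 0.28 and 0.58 in the normal tissue of animal 3229. Trp63 and Krt14 are higher and Tesc and Spdef lower in adenosquamous than in ErbB2-type tumors.

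Inflammatory cytokine genes stood out among the lists. Of 20 measured, 7 rose (11 adjusted over the list alone), led by the neutrophil chemokines Cxcl5 (4.16 ± 0.46, SE) and Cxcl1 (3.37 ± 0.41). The inflammatory list had a median difference of 0.90 (adjusted p = 1.73e-06; adjusted p = 0.0212 with an estimated correlation, the 1 list call of 7 that held), of 0.91 with run as a block and of 0.91 within run 2, the run with 2 tumors of each histology. The macrophage and lymphocyte lists had medians of 0.15 and -0.10 with no member called. Of 26 Wnt pathway genes 7 rose (11 adjusted over the list alone), led by Axin2 and the Wnt inhibitor Apcdd1 (3.39 ± 0.58; another probe -0.10). The Wnt list had a median of 0.41 (adjusted p = 0.00204; adjusted p = 0.348 with an estimated correlation), of 0.45 with run as a block and of 0.38 within run 2. Of 28 squamous genes 4 rose (5 adjusted over the list alone), including the desmosomal plakophilin Pkp1 (2.22 ± 0.31) and the keratinocyte protein Krtdap (0.92 ± 0.21). The squamous list had a median of 0.27 (adjusted p = 0.00138; adjusted p = 0.348 with an estimated correlation), of 0.22 with run as a block and of 0.26 within run 2.

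Of the markers that separate human breast cancer subtypes few passed, and neither list call held with an estimated correlation. Of 18 human basal markers 3 rose (4 adjusted over the list alone), including the basal keratins Krt14 (2.23 ± 0.36, SE) and Krt17 (1.30 ± 0.25). The human basal list had a median of 0.32 (adjusted p = 0.0429; adjusted p = 0.571 with an estimated correlation), of 0.31 with run as a block and of 0.28 within run 2, and its call was lost with run as a block and with scale normalization. Of 13 human luminal markers Spdef alone fell (-1.77 ± 0.29; also 1 adjusted over the list alone). The human luminal list had a median of -0.15 (adjusted p = 0.0449; adjusted p = 0.348 with an estimated correlation), of -0.10 with run as a block and of -0.09 within run 2, and its call was lost with median centring. Respiratory chain and interferon transcripts were lower as sets at the preset correlation alone. Of 26 oxidative phosphorylation genes 2 fell (also 2 adjusted over the list alone), Cox7a2 of complex IV (-1.23 ± 0.30) and Ndufs3 of complex I (-0.85 ± 0.17). The call of Cox7a2 was lost with median centring, the deposited table and scale normalization, and those of Axin2, Krt17 and Prr9 with median centring. The oxidative phosphorylation list had a median of -0.29 (adjusted p = 0.000227; adjusted p = 0.685 with an estimated correlation), of -0.39 with run as a block and of -0.41 within run 2. No interferon gene of 23 passed alone (0 adjusted over the list alone). The interferon list had a median of -0.70 (adjusted p = 0.0014; adjusted p = 0.72 with an estimated correlation), of -0.69 with run as a block and of -0.81 within run 2.

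In the 20 other lists the set test did not pass. Members rose in the basal and myoepithelial list (5 of 19), the hypoxia list (2 of 20, 3 adjusted over the list alone) and with 1 gene each in the mesenchymal (of 25), milk (of 16), Notch (of 13), luminal epithelium (of 20, 2 alone) and growth factor lists (of 22, 1 up and 1 down alone). Members fell in the lipid synthesis list (2 of 23) and the housekeeping list (1 of 10). None (0) changed among 16 fat cell, 14 endothelial (2 rose alone), 20 fibroblast, 15 macrophage, 17 lymphocyte, 12 skeletal muscle (1 rose alone), 4 erythrocyte, 13 antigen presentation, 16 MAP kinase output, 21 immediate early and 33 proliferation genes. Median, mean and test differed in sign for the proliferation (0.04, 0.07, down), growth factor (0.08, 0.19, down), housekeeping (0.17, 0.13, down) and skeletal muscle lists (-0.10, 0.11, down).

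The number of differing genes was 363 without tumor 3229, 332 without tumor 5154, 885 without the ErbB2-type tumor 5033, 661 with the spread from the 8 tumors alone, 786 with scale normalization, 649 within run 2 and 1869 with run as a block. Of 24 named genes called, 10 were called with any tumor left out. Without tumor 3229 the calls of Apcdd1, Armcx4, Axin2, Ehd3, Krt17, Krtdap, Ndufs3, Papln, Prr9, Tspan13 and Wdr72 were lost, and without tumor 5154 those of Armcx4, Atp1b1, Cox7a2, Krt17, Ndufs3, Sostdc1 and Wdr72, with Axin2 between 1.74 and 6.33, Prr9 between 0.93 and 6.90, Krtdap between 0.33 and 1.53, Ehd3 between -3.52 and -1.43 and Cox7a2 between -1.77 and -0.69.

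The third comparison asked whether the change from normal to tumor itself differed between adenosquamous and ErbB2-type animals. In limma 4 genes passed, and they are listed in full, including those outside the naming rule. Tesc differed between tumor and normal by 3.62 ± 0.41 (SD, n = 6) in ErbB2-type and by 0.28 ± 0.29 (n = 2) in adenosquamous animals, a difference of -3.34 ± 0.30 (SE; adjusted p = 0.0434). Cfi, the complement protease factor I, gave 1.92 ± 0.13 in adenosquamous and -0.40 ± 0.24 in ErbB2-type animals, a difference of 2.32 ± 0.20 (adjusted p = 0.0434). The clone-named transcripts 4732416N19Rik and TC1482443, chosen after their values were seen, differed by 3.12 ± 0.30 and 2.43 ± 0.24 (adjusted p = 0.0486 for both). Of 26339 genes tested these 4 differed (3 up and 1 down), with 3196 at an unadjusted p under 0.05. Met differed by -0.58 ± 0.42 (adjusted p = 0.685), Erbb2 by -0.21 ± 0.31 (adjusted p = 0.886) and Hgf by -0.04 ± 0.25 (adjusted p = 0.982). The other Tesc probe gave 0.01.

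As sets at the preset correlation, inflammatory and Wnt genes had a higher tumor change in adenosquamous animals, although no single member of any list passed over all genes. The inflammatory list differed by a median of 0.98 (adjusted p = 5.26e-08; adjusted p = 0.137 with an estimated correlation), and 7 of 20 members rose adjusted over the list alone. The Wnt list differed by 0.31 (adjusted p = 6.93e-05; adjusted p = 0.519 with an estimated correlation), with 9 of 26 up adjusted over the list alone. Mesenchymal genes differed by 0.55 (adjusted p = 0.00432; adjusted p = 0.805 with an estimated correlation; 0 of 25) and squamous genes by 0.14 (adjusted p = 0.0473; adjusted p = 0.805 with an estimated correlation; 3 of 28 up adjusted over the list alone), a call lost with the deposited table. List medians by animal were 0.49 (3229) and 0.61 (5154) for inflammatory genes, against -0.37 to 0.02 in ErbB2-type animals, while both adenosquamous animals differed more from each other in the Wnt, mesenchymal and squamous lists. They were 0.32 and 0.06 for Wnt genes (ErbB2-type -0.30 to 0.08), -0.24 and 0.34 for mesenchymal genes (-0.74 to 0.02) and 0.39 and 0.02 for squamous genes (-0.21 to -0.03). Oxidative phosphorylation genes differed by -0.54 (adjusted p = 8.35e-05; adjusted p = 0.805 with an estimated correlation; 0 of 26). Their medians by animal were -0.23 (3229) and -0.39 (5154), and overlapped with those of ErbB2-type animals (-0.33 to 0.68). Among the other cell types, the fibroblast list differed by 0.52 (adjusted p = 0.148), the fat cell list by -0.29 (adjusted p = 0.391) and the macrophage list by 0.08 (adjusted p = 0.371). None (0) of the 5 list calls held with an estimated correlation. In the 22 lists with no call, 0 members passed over all genes, and adjusted over the list alone 5 of 19 basal and myoepithelial genes rose. Adjusted the same way, 1 gene rose in each of the antigen presentation, macrophage and skeletal muscle lists, 1 rose and 1 fell in each of the hypoxia and luminal epithelium lists, and 1 fell in each of the housekeeping, human luminal and lipid synthesis lists. Median, mean and test differed in sign for the basal and myoepithelial (-0.06, 0.42, up), lipid synthesis (0.07, -0.28, down), hypoxia (-0.02, 0.13, up), skeletal muscle (-0.23, -0.06, up), growth factor (-0.05, 0.12, up) and immediate early lists (-0.02, 0.13, up).

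No run held complete pairs of both histologies, so no value within a run can be given, and the 6 pairs in 1 run gave 0 genes (2771 unadjusted, limma). The count was 0 with the processed signals (3117 unadjusted), the deposited table (3064) and scale normalization (2790), 9 with median centring, 0 without animal 4164 (3153 unadjusted) or 4691 (2748), 18 without 5154, 43 without 3229 and 85 without 5156. The call of Tesc was lost without animals 3229, 4164, 4691 and 5154 (-3.54 to -3.13) and that of Cfi without 4164, 4691, 5033 and 5154 (2.23 to 2.42).

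The fourth comparison joined both array designs to set all 8 carcinomas of other histologies against the 6 ErbB2-type carcinomas. Cyp26b1, which degrades retinoic acid, was 10.7-fold higher, and Aldh1a3, which makes it, 9.68-fold higher. Lmo1, a LIM-domain transcription regulator, was 11.1-fold higher. Gata3, a transcription factor of luminal cells, was 4.32-fold lower, a call lost without any 1 of 5 tumors. As sets 11 lists passed at the preset correlation, and none (0) of them did with an estimated correlation (adjusted p = 0.259 to 0.701). Of 25118 genes tested with limma, 1755 differed (1085 up, 61.8%, and 670 down), 690 of them at least 2-fold (392 up and 298 down), with 6123 at an unadjusted p under 0.05. The balance was 938 up and 900 down (51.0% up) with the deposited tables and 298 up and 1549 down (16.1% up) with median centring in place of loess.

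Met was on average higher in the other carcinomas but was not called (1.504 ± 0.76, SE; adjusted p = 0.228, limma, n = 8 and 6), with levels, adjusted for array design, of 0.47 ± 1.99 (SD) against -1.03 ± 0.63. Both other Met probes gave 0.90 and 1.24. Erbb2 differed by -0.05 ± 0.19 (adjusted p = 0.907) and Hgf by -0.14 ± 0.35 (adjusted p = 0.839). Lmo1 rose by 3.47 ± 0.54 (adjusted p = 0.0014), Cyp26b1 by 3.42 ± 0.51 (adjusted p = 0.00099) and Aldh1a3 by 3.27 ± 0.68 (adjusted p = 0.0075; another probe 2.98). St6gal1 rose by 3.18 ± 0.62 (another probe 0.09), Fads3, of the fatty acid desaturase family, by 2.66 ± 0.35 (adjusted p = 0.000281) and Ppp1r9a, a scaffold protein, by 2.70 ± 0.70 (5 other probes -0.37 to 0.53). The calcium-binding proteins S100a8 and S100a6 rose by 2.82 ± 0.67 and 2.81 ± 0.56. Tspan13 changed by -2.95 ± 0.32 (adjusted p = 7.59e-05) and Tesc by -3.13 ± 0.41 (adjusted p = 0.000281; another probe 0.10). Tox3 changed by -3.38 ± 0.56 and Apof, an apolipoprotein, by -2.97 ± 0.44, both below the presence limit in some profiles (9 and 5). Id2, an inhibitor of helix-loop-helix factors, changed by -2.42 ± 0.44 (another probe -1.03), Car6, a secreted carbonic anhydrase, by -2.63 ± 0.37 and Palmd by -2.39 ± 0.66 (another probe -0.0016).

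Of 20 inflammatory genes 5 rose (9 adjusted over the list alone), led by S100a8 and Cxcl5 (2.52 ± 0.75, SE). The inflammatory list had a median of 1.37 (adjusted p = 0.00418; adjusted p = 0.259 with an estimated correlation), of 0.91 within run 2 of the first design and of 0.36 within the second design. Here and below, the second-design value sets 6 carcinomas against a single ErbB2-type tumor, which was in another run and had the lowest dye-swap correlation (0.823). Of 26 Wnt pathway genes 5 rose (6 adjusted over the list alone), including Axin2 (2.89 ± 0.73) and Apcdd1 (2.43 ± 0.56; another probe 0.05). The Wnt list had a median of 0.69 (adjusted p = 0.0464; adjusted p = 0.589 with an estimated correlation), of 0.38 within run 2 and of 0.72 within the second design. Of 27 squamous genes Pkp1 alone rose (2.14 ± 0.36; also 1 adjusted over the list alone). The squamous list had a median of 0.32 (adjusted p = 0.00754; adjusted p = 0.592 with an estimated correlation), of 0.27 within run 2 and of 0.36 within the second design. Of 23 interferon genes 0 passed (0 adjusted over the list alone). The interferon list had a median of -0.79 (adjusted p = 0.00418; adjusted p = 0.696 with an estimated correlation), of -1.36 within run 2 (-0.81 for the same tumors on the probes chosen in the second comparison) and of -0.86 within the second design. Of 23 lipid synthesis genes 3 fell (also 3 adjusted over the list alone), including the fatty acid elongase Elovl5 (-1.09 ± 0.23, another probe -0.37) and the sterol reductase Dhcr7 (-1.05 ± 0.31, another probe -0.15). The lipid synthesis list had a median of -0.15 (adjusted p = 0.0402; adjusted p = 0.696 with an estimated correlation), of -0.17 within run 2 and of -0.38 within the second design. The lipid synthesis call was lost with the processed signals, the deposited tables and scale normalization, the squamous call with the first and last of these and the Wnt call with scale normalization.

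Of the human subtype markers few passed. The call of the human basal list was lost with the processed signals, median centring and scale normalization, and that of the human luminal list with the first 2 of these. Of 12 human luminal markers 2 fell (3 adjusted over the list alone), Gata3 (-2.11 ± 0.59, SE) and Spdef (-2.04 ± 0.23, adjusted p = 9.34e-05). The human luminal list had a median of -0.31 (adjusted p = 0.0144; adjusted p = 0.259 with an estimated correlation), of -0.09 within run 2 and of -0.17 within the second design. Of 18 human basal markers 1 rose and 1 fell (6 and 2 adjusted over the list alone): Krt14 by 1.74 ± 0.37 (call lost with median centring and scale normalization) and the forkhead factor Foxc1 by -1.35 ± 0.41. The human basal list had a median of 0.49 (adjusted p = 0.0493; adjusted p = 0.589 with an estimated correlation), of 0.28 within run 2 and of 0.45 within the second design. At the preset correlation lists of vessel, macrophage and connective tissue genes were higher, and the endothelial and macrophage calls were lost with scale normalization. Of 14 endothelial genes 2 rose (7 adjusted over the list alone), Kdr, a receptor for vascular growth factor (1.62 ± 0.39; another probe -0.13, and -0.80 with scale normalization), and Robo4 (1.24 ± 0.33). The endothelial list had a median of 1.07 (adjusted p = 0.00418; adjusted p = 0.696 with an estimated correlation), of 0.35 within run 2 and of 1.49 within the second design. Of 15 macrophage genes 3 rose (5 adjusted over the list alone), including the complement chains C1qb (1.59 ± 0.38) and C1qa (1.51 ± 0.38). The macrophage list had a median of 0.64 (adjusted p = 0.00418; adjusted p = 0.619 with an estimated correlation), of 0.27 within run 2 and of 0.86 within the second design. Of 20 fibroblast genes 0 passed (0 adjusted over the list alone). The fibroblast list had a median of 0.88 (adjusted p = 0.00718; adjusted p = 0.701 with an estimated correlation), of 0.45 within run 2 and of 1.13 within the second design. Of 25 mesenchymal genes 2 rose (also 2 adjusted over the list alone), the membrane protease Mmp14 (2.29 ± 0.60; another probe -0.17) and Snai2 (1.69 ± 0.49). The mesenchymal list had a median of 0.47 (adjusted p = 0.0171; adjusted p = 0.696 with an estimated correlation), of 0.47 within run 2 and of 0.34 within the second design, and its call was lost with median centring.

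In the 16 other lists the set test did not pass. Rises and falls numbered 2 and 1 of 19 basal and myoepithelial genes (4 and 1 adjusted over the list alone), 3 and 1 of 20 luminal epithelium genes, 3 and 1 of 23 growth factor genes (5 and 3 alone), 1 and 3 of 16 MAP kinase output genes (1 and 5 alone) and 2 and 1 of 20 hypoxia genes (3 and 3 alone). They numbered 1 and 2 of 26 oxidative phosphorylation genes (1 and 5 alone), 0 and 2 of 13 antigen presentation genes, 1 and 0 of 21 immediate early genes (2 and 1 alone), 1 and 0 of 16 milk genes (2 and 0 alone), 1 and 0 of 12 skeletal muscle genes, 0 and 1 of 14 Notch genes and 0 and 1 of 17 lymphocyte genes. None (0) passed among 16 fat cell, 33 proliferation, 4 erythrocyte and 10 housekeeping genes (1 housekeeping gene rose alone). Median, mean and test differed in sign for the immediate early (0.08, 0.03, down) and erythrocyte lists (0.04, 0.18, down). None (0) of the 11 list calls held with an estimated correlation.

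Run and histology overlap in this comparison, because run 4 held all 6 second-design carcinomas and no ErbB2-type tumor: 778 genes differed with run as a block (85.6% up, 264 of them shared with the 1755), 966 with run as a random block, 829 with slide as a random block, 33 within the second design (6 against 1 tumor) and 5023 without the design term. The count was 1100, 1109 and 1126 without the ErbB2-type tumors 4691, 4164 and 559, and 1750 without the microacinar carcinoma, whose skeletal muscle list stood at 3.39 and fibroblast list at 1.21. Among the fits without 1 tumor it was highest, at 2369, without the papillary carcinoma, which shares animal 5033 with an ErbB2-type tumor. Of 31 named genes called, 19 were called with any tumor left out, while Cxcl5 and Dhcr7 lost their calls in 9 of 14 fits, Foxc1 in 8, Snai2 in 7, Gata3 and Palmd in 5, and C1qa, C1qb (0.96), Mmp14, Ppp1r9a (1.72), Robo4 (without tumor 4164) and Aldh1a3 (without tumor 5156) in 1. Calls were also lost under another scaling: C1qa and Dhcr7 with the processed signals, C1qa, Cxcl5, Kdr, Mmp14, Robo4 and Snai2 with median centring, Kdr and Robo4 with the deposited tables, and C1qa, C1qb, Kdr, Ppp1r9a, Robo4 and S100a6 with scale normalization.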

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

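The tests of the run and of other cell types behind the lower markers in tumors, and the test for a faulty Met probe, were chosen only after the result was seen.

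Several genes had 1 animal or tumor far from the rest of its group, given here with the gap to the nearest other value as a share of the whole range. Chance flags about 1 in 20 groups, and 13 of 113 groups tested had such a gap: 6 of 40 sets of pair differences of genes, 2 of 27 sets of ErbB2-type tumors, 5 of 34 sets of adenocarcinomas and 0 of 12 sets of list shifts. Animal 3229, with adenosquamous carcinoma, had the smallest tumor rise of Etv1 (1.14, nearest 3.03, share 0.537) and of Col11a1 (0.29, nearest 2.55, share 0.542). Animal 5154, the other with adenosquamous carcinoma, had the smallest fall of Armcx4 (-0.45, nearest -2.87, share 0.501). Animal 562, with the pre-invasive lesion, had lower Egr3 in the lesion than in the normal tissue (-1.43, nearest 1.40, share 0.498). Animal 4164 had the smallest fall of Rspo1 (-0.30, nearest -2.94, share 0.550) and animal 6696 the deepest fall of Hgf (-1.11, nearest -0.66, share 0.514).

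Among the ErbB2-type tumors, Cxcl5 was highest in tumor 6696 (-2.66, nearest -3.60, share 0.693) and Apcdd1 in tumor 559 (-1.80, nearest -2.87, share 0.728). Among the 4 adenocarcinomas, tumor 567 had the lowest St6gal1 (-1.49, nearest 1.59, share 0.906) and the highest Tspan13 (2.56, nearest 1.46, share 0.848). Tumor 4425 had the lowest Palmd (2.81, nearest 5.56, share 0.903), Krt14 (1.69, nearest 2.79, share 0.851) and Pkp1 (0.60, nearest 3.28, share 0.969).

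The change from normal to tumor differed between adenosquamous and ErbB2-type animals, by the test of the difference itself in limma, for Cfi (2.32), TC1482443 (2.43), 4732416N19Rik (3.12) and Tesc (-3.34). As sets it differed for the inflammatory (0.98), Wnt (0.31), mesenchymal (0.55), squamous (0.14) and oxidative phosphorylation lists (-0.54) at the preset correlation, while none (0) of these 5 calls held with an estimated correlation (adjusted p = 0.137 to 0.805). The histologies differ in run as well, since both adenosquamous pairs were in run 2 and no complete ErbB2-type pair was, so run and histology cannot be told apart for these values.

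Markers of fat, vessels and connective tissue were lower in tumors than in normals. Run alone is argued against for the fat cell list, since its mean shift over the 6 pairs in 1 run was -1.20 ± 0.838 (SD). A candidate explanation is that normal captures held more cells other than epithelium: the mean shifts of the fat cell, endothelial, fibroblast, lymphocyte, macrophage and skeletal muscle lists were all below 0 (-1.51, -0.58, -0.77, -0.29, -0.23 and -0.55; n = 9), no gene of these lists is in another list, and Cfd stood at 6.05 in normals and 0.76 in tumors. The fibroblast, macrophage and skeletal muscle means lay within their SD of 0 (SD 0.81, 0.44 and 0.86). These shifts were above 0 in 2, 2 and 4 of 9 pairs, against 0 pairs in the other lists. The endothelial and fibroblast shifts correlated over the 9 pairs at 0.474 (exact permutation p = 0.1985, adjusted 0.596; rank correlation 0.417; 0.161 without the 2 farthest pairs; 0.446 in the 6 pairs in 1 run), while the fat cell shift correlated with them at 0.162 and 0.0251 (-0.528 and -0.208 in the 6 pairs in 1 run), so a shared source is left open, as is an untested change in the tumor itself. Chance alone is argued against for the number of changed genes: 1 of 100 drawn sign changes of the pairs (256 possible), the real one, gave as many (3428 of 23662 genes measured in every pair, highest other 241).

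Genes differed between the other carcinomas and ErbB2-type carcinomas across both array designs. Design or run as the whole cause is argued against: of 1921 genes called for the 6 second-design carcinomas against 4 ErbB2-type tumors, 75.8% had the same direction in the adenosquamous tumors against the other 2 ErbB2-type tumors within run 2 of the first design (79.6% of rises and 70.6% of falls, against 57.2% of the genes not called). Wider ratios on the second design stay open: the 2 tissues on both designs gave spread ratios of 0.982 and 1.201, so rescaling by their mean of 1.09 (1811 genes, against 1755) was too small a correction to decide. Scale normalization gave 1674 genes, 887 of them among the 1755. It was run within each design, so it left a difference in spread between the designs in place and cannot decide this either. Chance alone is argued against: 1 of 100 drawn splits of the 14 tumors (3003 possible), the real one, gave as many genes (1157 of 21272, highest other 12). The drawn splits mixed runs, while the real split put all 6 second-design carcinomas, of run 4, in 1 group. A run effect could therefore also raise the real count, and the splits cannot separate run from histology. Part of the calls remains confounded with run, because 778 genes differed with run as a block, and a difference between histologies stays open as untested beyond this.

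Met stood far above the other second-design tissues in tumors 4425 and 5612 (3.44 and 3.32 above the median of the 8 tissues) and less so in tumor 5482 (2.04). The dye orientations of this probe differed widely in size. With the tissue in green the deviations were 1.29 (4425) and 1.34 (5612), and with the tissue in red 5.58 and 5.30. A single faulty probe or array is argued against, since 10 of the 12 deviations over 3 probes and 2 dye orientations in tumors 4425 and 5612 were over 2 (1.29 to 5.58). The deviations under 2 were those of the probe behind the reported Met values, with the tissue in green. Both other probes lay over 2 in both orientations. A candidate explanation is gain of the chromosome segment around Met: the median deviation of the 10 nearest measured genes was 2.52 ± 0.97 in tumor 4425, 4.12 ± 0.63 in tumor 5612 and 1.46 ± 0.51 in tumor 5482, against -0.62 to -0.02 in the other 5 tissues and -0.75 to 0.57 for tumor minus normal in the first-design pairs (n = 9). Each ± value here is the SE of the mean over the 10 genes within 1 tumor, not a spread over tumors. Not every neighbour was raised (Mdfic -0.70 and Wnt2 -1.27 in tumor 4425), and for tumor 5482 the evidence is weak: St7 (-0.18), Cttnbp2 (-1.40) and Lsm8 (-0.34) were not raised, the Met deviations were 0.53 to 2.68 over probes and dye orientations, and its skeletal muscle and fibroblast lists stood at 3.39 and 1.21, so other cells stay open there as an untested source. DNA was not analysed here, so the hypothesis rests on transcripts of the same arrays on which the pattern was seen.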

How the results depend on the processing

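Chosen only after the result was seen were: scale normalization, rescaled second-design ratios, slide as a block, run as a block (planned for tumor against normal alone), single runs, the 6 pairs in 1 run, omission of the 3 animals with muscle transcripts or of the 2 profiles of lowest dye-swap correlation, median centring and the deposited table for lists and named genes, and these 2 and Aquantile for the difference of the tumor change. Of 96 alternative counts of genes 57 were within 1.5 times the reported count, of 229 list tests 175 kept direction and call while 54 lost the call, and of 1707 values of named genes 1512 kept both, 149 lost the call and 46 reversed. Unless a smaller number of samples or a stricter threshold is named, the cause was not tested. Signal over background limits the second design, at 5.04 against 9.85 on the first.

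Without the replicate block, that is without the pairing by animal, 4327 genes changed between tumor and normal and 1351 between adenosquamous and ErbB2-type tumors, and with the animal as the block across both designs 1436 differed.

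For tumor against normal (3632), sets of 6 animals, which change both the number of animals and which ones are kept, gave 1682 genes in the 6 ErbB2-type animals, 666 in the 6 pairs in 1 run, and 346 without the 3 animals with muscle transcripts (the cause was not tested). Fewer samples and no pairing by animal together gave 656, 118 and 0 within runs 1, 2 and 3 (3387 unadjusted for the 0, limma), while a 2-fold minimum gave 953, and leaving out 1 animal gave 1763 to 3535. For adenosquamous against ErbB2-type carcinoma (1349), median centring gave 342, scale normalization 786, the 8 tumors alone 661, run 2 alone 649, a 2-fold minimum 441 and leaving out 1 tumor 332 to 1660. For the difference of the tumor change (4), the processed signals, the deposited table, scale normalization and the 6 pairs in 1 run each gave 0 (3117, 3064, 2790 and 2771 unadjusted, limma), median centring 9 and leaving out 1 animal 0 to 85. Across both designs (1755), dropping the design term gave 5023, the second-design carcinomas alone 3682, the second design alone 33, run as a random block 966, run as a block 778, slide as a random block 829, a 2-fold minimum 690 and leaving out 1 tumor 1100 to 2369.

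With an estimated correlation the list calls went from 12 to 0, from 7 to 1, from 5 to 0 and from 11 to 0 in the order of the report. Across both designs 7 lists were called with the processed signals, each among the 11, and 7 with scale normalization, 5 of them among the 11. Cfi and Tesc, called for the difference of the tumor change, were 0 of 2 with the processed signals, the deposited table and scale normalization.

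Reversed values under another scaling were those of Met between adenosquamous and ErbB2-type tumors (-0.039, median centring), Hgf for the difference of the tumor change (0.063, scale), Erbb2 across both designs (0.023, processed signals; 0.12, scale), Hgf across both designs (0.76, processed signals; 0.013, deposited table) and Kdr across both designs (-0.80, scale). Of these Kdr alone had been called. Leaving out 1 tissue or animal moved Hgf from -0.13 to 0.053 and Met from -0.53 to 0.62 between adenosquamous and ErbB2-type tumors, Erbb2 from -0.33 to 0.40 and Hgf from -0.20 to 0.11 for the difference of the tumor change, and Erbb2 from -0.12 to 0.068 across both designs.

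Other probes of the same gene gave the opposite sign for tumor against normal in Acta2 (0.19, 0.39 and 0.0018), Cenpa (-0.13), Chl1 (-0.14), Egr3 (-0.18), Erbb2 (0.021), Met (0.048 and 0.19), Pfkp (-0.0056) and St8sia6 (-0.60). They did so between adenosquamous and ErbB2-type tumors in Apcdd1 (-0.10), Erbb2 (0.16 and 0.089), Met (-0.0051) and Palmd (0.17), and for the difference of the tumor change in Erbb2 (0.40), Met (0.042 and 0.037) and Tesc (0.0063). Across both designs they did so in Erbb2 (0.20 and 0.073), Hgf (0.012), Kdr (-0.13), Mmp14 (-0.17), Ppp1r9a (-0.37) and Tesc (0.10).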

Other observations

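Single tissues of the second design differed in their lists, and these values belong to no comparison of the report. The microacinar carcinoma with squamous areas had a median log2 ratio of -0.08 for luminal epithelium genes, 3.39 for skeletal muscle genes, 1.21 for fibroblast genes and 0.21 for mesenchymal genes. The 4 adenocarcinomas had luminal medians of 1.23 to 2.20, fibroblast medians of -1.92 to -0.32 and mesenchymal medians of -1.81 to -1.12. Their interferon medians were 2.52, 1.04, 1.89 and 0.27 in tumors 4425, 4695, 5612 and 567, while the microacinar carcinoma had -1.07 and the papillary carcinoma -0.41. The papillary carcinoma had a fibroblast median of -2.87 and an immediate early median of 1.39. Tumor 4695 had a skeletal muscle median of 1.59.

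The single pre-invasive lesion, of animal 562, had medians of 1.38 for luminal epithelium, 0.12 for basal and myoepithelial, -2.76 for fibroblast and -1.81 for proliferation genes.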
